A study of Mus musculus with 8 samples.

How the data were processed

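Total RNA of right cortex from 4 dMCAO and 4 sham male mice was measured on 8 single-colour (Cy3) Agilent arrays, 1 array per mouse. Groups and replicate numbers were taken from the sample titles. The labels describe each sample as a separate one and the design text counts 8 mice. The treatment and extraction texts of the labels describe irradiated human blood, which does not match the mouse cortex named elsewhere in the labels, so they were not used.

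The scanner files deposited by the authors hold a spot intensity on a linear scale, background-subtracted and detrended within the array and not normalized between arrays, made with Agilent Feature Extraction 12.0.3.1 per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.1 instead. The raw spot mean and local background median intensity in the same files were used for 1 alternative. A value table deposited by the authors holds log2 values, whose normalization is not given in the sources used here. Set against the scanner values of the same array, each of its columns correlated with r between 0.998 and 0.999 across probes, and the median of each column was 6.44, so its scale and direction are those of log2 signal; its centring between arrays remains unknown and resembles quantile normalization. All 90752 probes of the scanner files matched a row of that table by probe ID.

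Control spots and spots marked as outliers by the scanner software (12 to 57 per array) were left out. The processed signal was taken to log2, and each array's 75th percentile over all non-control spots was subtracted. The spots of a probe were averaged: 85274 probes had 2 spots and 5478 had 1. A probe was tested when all its remaining spots were well above background on at least 4 of the 8 arrays, whatever the group, which kept 64086 probes, 70.6% of all. This held on no array for 23049 probes and on all 8 for 58921. The SD between duplicate spots was 0.15 to 0.19 on the log2 scale, with a median over probes of 0.06 to 0.08.

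Groups were compared with limma 3.58.1 in R 4.3.3 (linear model and empirical Bayes moderation, all 8 arrays, no covariates), with Benjamini-Hochberg adjustment over the tested probes and a threshold of adjusted p under 0.05. Tested on simulated data with 200 of 64086 probes changed, the fit recovered 21.5% of changes of 0.5, 87% of changes of 1 and 100% of changes of 2 on the log2 scale, with 3, 2 and 9 false calls. Far more probes, 7456, passed the threshold in the real comparison. The adjustment depends on that number, so these shares need not hold there. Probes named in the text passed the threshold, were well above background on all 8 arrays and had fully separated groups, and of the 6476 probes meeting this rule the 2 with the largest rise and the 2 with the largest fall were taken. The rule was written before the data were examined; it named genes, and because the files pair no probe with a gene, probe IDs stand in their place and their number was held to 4.

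Comparisons fixed before the data were examined that need gene names were not made: the split into coding and noncoding transcripts, the tests of 41 gene lists and the averaging of several probes of a gene. The gene table at hand, of assembly GRCm38.p6, pairs no entry with these probe IDs. Overlapping probes were found from their sequences as probes sharing a run of at least 25 bases on the same strand. No pair of arrays held identical values, and the highest correlation between arrays was 0.997.

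Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter of all 8 arrays, a trended and robust empirical Bayes fit, array weights, a replicate block, the deposited value table, each array left out in turn, a threshold of 2-fold added and an adjusted p under 0.01. A slide block could not be fitted because each slide held 1 group. Random lists were matched to a list of probes on the number of G and C bases and on the decile of mean signal, with 10000 lists drawn. Sequences and figures were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and spot files in R with version 1.17.8 of the data.table package.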

Results

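RNA from the right cerebral cortex of 8 male mice was hybridised to single-colour arrays designed for mouse long noncoding RNA (lncRNA). In 4 mice the tissue was the cortex bordering an infarct after dMCAO, the usual abbreviation of distal middle cerebral artery occlusion, a surgical model of focal ischaemic stroke in which a branch of that artery is closed over the cortex. In the other 4 mice, sham controls, it was the corresponding right cortex. The time between surgery and sampling was not given in the sources used here. Each array held 176026 non-control spots for 90752 probes of 60 bases. Between 67.9% and 74.6% of the non-control spots of an array were well above background, and no spot was saturated. The 75th percentile of signal lay between 523 and 631. The files give each probe an ID and a sequence and pair neither with a gene name or a genome position, so the results are stated for probes, for sets of probes with overlapping sequence and for groups of probes defined by size of change or signal. The number of arrays, 4 per group, limits the precision of every value.

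The one comparison of the design was between peri-infarct cortex and sham cortex, and it addressed which transcripts on the array differ in level after stroke. In peri-infarct cortex 4014 probes were higher and 3442 lower than in sham cortex, which together made up 11.6% of the 64086 probes tested (limma, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Most of these differences were small: the median was 0.52 on the log2 scale among the higher probes and −0.43 among the lower ones, and 89.1% of the 7456 probes lay under 2-fold. The larger differences went mostly upwards. At least 2-fold, 699 probes were higher and 114 lower, so that 86.0% of these 813 probes were higher. These are fitted folds: in 105 of the 699 no sham array, and in 14 of the 114 no dMCAO array, was well above background, so that their size is open, and normexp on the raw spot means with an offset of 50 left 299 higher and 24 lower. Among probes well above background on all 8 arrays, 448 were at least 2-fold higher and 74 lower (85.8% higher), 72 were at least 4-fold higher and 1 lower, and 21 were at least 8-fold higher and 0 lower.

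Over all probes past the threshold the division into higher and lower was near even and depended on the scaling: 53.8% were higher with 75th percentile scaling, 49.7% with quantile normalization and 49.1% in the submitters' own values. Each slide held arrays of 1 group only, and each slide was scanned in its own session, so slide, scan and group cannot be told apart.

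Among the probes well above background on all 8 arrays, with groups that did not overlap, the 2 largest rises were those of MOUSELNCRNA_77140 and MOUSELNCRNA_86204 and the 2 largest falls those of MOUSELNCRNA_1288 and MOUSELNCRNA_50551. MOUSELNCRNA_77140 (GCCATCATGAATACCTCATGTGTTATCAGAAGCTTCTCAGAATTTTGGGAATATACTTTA) was 31.7-fold higher in peri-infarct cortex, with a log2 difference of 4.99 ± 0.28 (SE, n = 4 per group; limma adjusted p = 2.90e-05). Its processed signal lay between 1108 and 2313 in the dMCAO arrays and between 31.9 and 86.7 in the sham arrays, where the negative control spots had median processed signals of 2.98 to 3.66. With normexp on the raw spot means and an offset of 50 the log2 difference was 3.78. MOUSELNCRNA_86204 (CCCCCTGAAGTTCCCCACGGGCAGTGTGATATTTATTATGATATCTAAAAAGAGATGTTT) was 30.4-fold higher, by 4.93 ± 0.28 on the log2 scale (SE, n = 4 per group; limma adjusted p = 3.01e-05). It was the brighter of the pair, with signals from 5373 to 9914 in the dMCAO arrays and from 139.8 to 446 in the sham arrays.

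MOUSELNCRNA_1288 (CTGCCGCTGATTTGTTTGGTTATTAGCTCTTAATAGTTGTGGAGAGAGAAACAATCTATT) was 4.26-fold lower in peri-infarct cortex, with a log2 difference of −2.09 ± 0.29 (SE, n = 4 per group; limma adjusted p = 0.00286). Its signal ranged from 482 to 1042 in the dMCAO arrays and from 2066 to 4328 in the sham arrays. MOUSELNCRNA_50551 (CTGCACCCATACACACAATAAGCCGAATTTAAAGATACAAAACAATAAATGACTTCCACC), printed on the array in 1 spot, was 3.15-fold lower, with a log2 difference of −1.66 ± 0.35 (SE, n = 4 per group; limma adjusted p = 0.0178). Its signals were 240.4 to 670.1 in the dMCAO arrays and 748 to 1972 in the sham arrays.

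**Figure D1:**
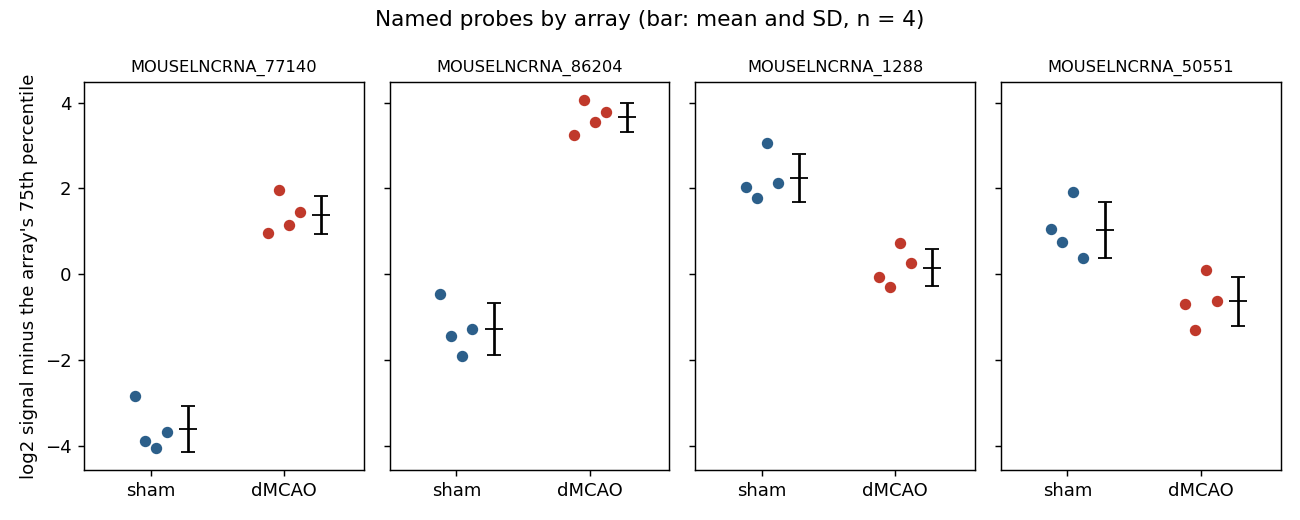
Log2 signal minus the array's 75th percentile (vertical axis) of the 4 named probes in the 4 sham and 4 dMCAO arrays; each point is 1 array, and the black bars give the mean and SD of a group. For MOUSELNCRNA_77140 and MOUSELNCRNA_86204 all 4 dMCAO arrays lie above all 4 sham arrays, and for MOUSELNCRNA_1288 and MOUSELNCRNA_50551 all 4 lie below.

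A further group of probes was well above background in 1 group of mice only, and for these only a bound on the change can be given. In 184 probes all 4 dMCAO arrays were well above background and no sham array was. Of these, 154 passed the threshold, 59 of them at least 2-fold higher and 19 at least 4-fold higher; the largest bound was at least 19.2-fold higher. In the opposite direction 20 probes were well above background in all 4 sham arrays and in no dMCAO array. All 20 passed the threshold, 11 of them at least 2-fold lower and 0 at least 4-fold lower, with a largest bound of at least 3.12-fold lower. Probes of both kinds were picked by this division of the arrays by group, so that most passed is no separate evidence of a difference. Each bound sets the mean of the brighter group against, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal of any probe well above background.

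**Figure D2:**
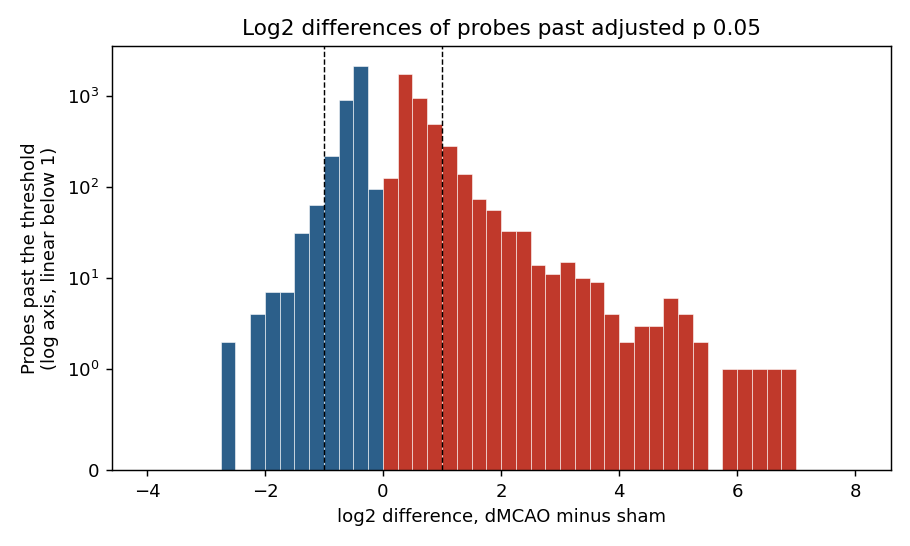
Number of probes past the threshold (vertical axis, logarithmic above 1) by fitted log2 difference between dMCAO and sham cortex (horizontal axis, bins of 0.25). Probes not well above background in 1 group are included. Bars right of 0 are probes higher in dMCAO and bars left of 0 are lower; beyond the dashed lines at 2-fold there are 699 higher and 114 lower probes.

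Probes of every brightness took part. With the tested probes ranked by mean signal into 4 equal bins, 11.1% of the dimmest bin and 11.5% of the brightest passed the threshold. At least 2-fold, 296 probes of the dimmest bin were higher and 64 lower, and in the brightest bin 84 were higher and 16 lower.

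Probes that share sequence moved together. The array held 3997 pairs of probes with at least 25 shared bases and no further overlapping probe, and in 2694 pairs both members were tested. Their log2 differences correlated across pairs (Pearson r = 0.878, Spearman rho = 0.860; probes are not independent replicates). In 463 pairs at least 1 member passed the threshold, and in 452 of these, 97.6%, both members had the same sign. In 260 pairs both members passed, all 260 in the same direction. With overlapping probes averaged into 1 feature, 3474 features were higher and 3096 lower.

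The 2 groups of mice were separated by the first principal component of the tested probes. That component held 50.3% of the variance, with the dMCAO arrays between 37.0 and 44.1 and the sham arrays between −60.4 and −19.7. The 4 arrays of one group lay wholly above or below those of the other for 20.1% of the tested probes, against 2.86% by chance, with 6554 higher and 6336 lower in dMCAO. The spread within a group was somewhat larger in sham cortex, with a median SD of 0.13 on the log2 scale against 0.11 in peri-infarct cortex, and sham had the larger SD in 58.2% of the probes.

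**Figure D3:**
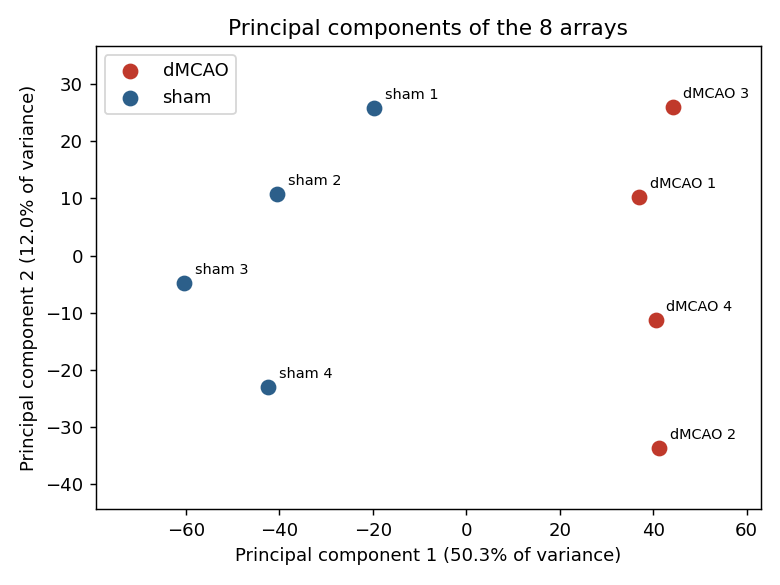
Scores of the 8 arrays on principal component 1 (horizontal axis) and principal component 2 (vertical axis), with the share of variance of each on the axis; each point is 1 array and the colour gives its group. The dMCAO arrays lie between 37.0 and 44.1 on component 1 and the sham arrays between −60.4 and −19.7, with sham 1 nearest to the dMCAO arrays.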

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

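In each group of 4 arrays the most extreme array was set against the others for 11 array measures and for the 4 named probes, 30 groups of values in all. In 0 of the 30 did the gap to the nearest array pass Dixon's 95% critical value as a share of the group's range, where chance alone gives about 1.5.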

How the results depend on the processing

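Averaging overlapping probes was chosen after seeing the data; the other alternatives were planned. The 4 named probes kept their direction and passed the threshold in 75 of 76 values over 19 alternatives, with adjusted p up to 0.0465; the exception was MOUSELNCRNA_50551, whose 0.0178 misses an adjusted p of 0.01. Every probe past the threshold both in the reported fit and in an alternative had the same direction in both. Fits to largely the same arrays leave little room for another outcome. The count of 4014 higher and 3442 lower probes moved more than 1.5 times without a filter on dim probes (2576 and 1914; 90746 probes tested), at an adjusted p under 0.01 (1493 and 857) and with a 2-fold minimum (699 and 114). Leaving out 1 array gave 2557 to 3941 higher and 1844 to 3273 lower probes; the larger drops came without dMCAO 1 (2666 and 1844), dMCAO 3 (2671 and 1954), sham 2 (2557 and 1918) and sham 3 (2620 and 2066), with fewer arrays in the fit. The replicate block left 2942 higher and 2220 lower probes. Same-numbered samples correlated by −0.02 to 0.04 in their deviations and 1 of 4 correlated best with its own number, so the numbers were not taken as pairs. In both groups the replicate number was also the position on the slide, so the block stood for position as well. The 699 and 114 probes at least 2-fold changed became 299 and 24 with normexp, run on the raw spot means and with an offset. Which of these was the cause was not tested. Where all 8 arrays had to be well above background, the 699 became 453. Of the probes at least 2-fold changed, 82.8% to 92.6% were higher under every alternative. A slide block and the gene-level alternatives were not run. Signal near background limits the changes that can be measured: 23049 probes were well above it, with all their spots, on no array.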

Other observations

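Of the tests in this part, those on matched lists, on A-rich arrangements and on the shift of probes with AATAAA were written before their results were seen; those on splits, spike-in controls, scaling and the background floor were chosen after, and the sets of related probes, the opposite strands and the hexamer were looked at only after the data had been seen.

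Probes fall into sets of related sequence, and 22 sets had at least 20 tested members. In a set of 71 related probes all 71 were higher in peri-infarct cortex, by a mean of 0.98 on the log2 scale. The mean of the set was 1.76 ± 0.25 in dMCAO and 0.78 ± 0.18 in sham (SD, n = 4 per group; log2 relative to the array's 75th percentile; exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 arrays allow, Benjamini-Hochberg adjusted over the 22 sets 0.126). Over the alternatives its mean log2 difference lay between 0.91 and 1.08 and 68 to 71 members passed the threshold, except that 23 passed with the 2-fold minimum and that the set counts as 1 feature, which passed, where overlapping probes were averaged. In a set of 22 related probes 21 were higher, by a mean of 0.47, but 0 passed at an adjusted p under 0.01 or with the 2-fold minimum, 1 with the replicate block, 13 without a filter, 9 without dMCAO 2 or without sham 2, and 12 without sham 4. 3 other sets also had arrays fully separated by group, all lower in dMCAO. These sets of 151, 58 and 24 probes had mean log2 differences of −0.16, −0.15 and −0.16, negative under every alternative. They held 27, 4 and 1 lower members past the threshold, and the set of 151 also held 1 higher one. The largest set, of 503 probes, differed by 0.09 on the log2 scale (exact permutation test, two-sided p = 0.143), and 0 of its members passed the threshold in limma. None of the 22 sets passed the adjusted exact test, and 5.95% of their 2253 members passed the threshold in limma, against 11.6% of all tested probes.

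Pairs of probes on opposite strands that share sequence were compared by their log2 differences, across pairs that are not independent replicates. Across 268 pairs from sets of at most 2 probes, Pearson r was 0.130 and Spearman rho 0.149, and 182 of 10000 shuffled pairings gave as high an r. The value depended on the sets admitted: r was 0.0960 over 327 pairs from sets of at most 4 (432 of 10000 shuffles as high) and 0.550 over 387 pairs from sets of at most 10 (0 of 10000), where it fell to 0.337 without the 2 most changed pairs. Both members passed the threshold in 4 of the 268 pairs, with the same sign in 3, and in 11 of the 387, with the same sign in 10.

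Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 7456 probes past the threshold. The highest of the others gave 55, but each of the others mixes dMCAO and sham arrays, so its count does not measure the calls expected by chance. The rank of the real split argues against chance assignment of arrays to groups but cannot exclude it, because 1 of 35 is the smallest share these splits allow. The real split is also the split by slide. The E1A controls, foreign sequences added to the RNA for labelling, were all higher in dMCAO over the 9 that were above background, by 0.06 to 0.196 on the log2 scale with a median of 0.07, against a median change of 0.47 among the probes past the threshold. Slide, labelling or scan cannot be told apart from stroke, because each slide held 1 group, and a slide effect on other sequences may contribute to the many changes under 2-fold. Tissue differences between dMCAO and sham cortex stay among the open explanations.

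Of the probes at least 2-fold changed, 86.0% were higher in peri-infarct cortex. The choice among the scalings tried is argued against as the cause: over normexp, quantile normalization, median scaling and the submitters' values the share was at least 84.2%. Under each of these the median log2 difference of the tested probes stayed near that of the reported fit (−0.016 to −0.024 against −0.007). A scaling fault common to them is therefore left open. A background floor that hides falls is argued against too, since among probes whose mean lies at least 8-fold above the floor 89.5% were higher (325 higher and 38 lower). The slide of each group remains open, and a biological excess of rises after dMCAO is a hypothesis that these arrays cannot separate from it.

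The hexamer AATAAA, the usual polyadenylation signal near the 3′ end of transcripts, stood in 229 of the 699 probes at least 2-fold higher, 32.8%, against 15.7% of the other tested probes. It was not particular to rises: over all probes past the threshold it stood in 24.4% of the higher and 18.5% of the lower ones, with 0 of 10000 matched lists as high in either case, and in 16.7% of the 114 at least 2-fold lower, within the range of matched lists. For the 699, base composition and brightness are argued against, since the middle 95% of matched lists reached up to 18.5%. AATAAA was raised over its matched lists by 16.9 percentage points (17.4 with 1 probe per overlapping set). The other arrangements of 5 A and 1 T were raised by at most 5.28 points. Of these, AAATAA (14.7% against 9.46% in matched lists) and ATAAAA (13.3% against 8.37%) were raised, with 1 and 0 of 10000 lists as high. The remaining arrangements lay within the middle 95% of their matched lists. A-rich sequence in general is thus argued against as the whole of the excess. Whether it forms a part cannot be told: AAATAA and ATAAAA overlap AATAAA when shifted by 1 base, and probes with AATAAA were not left out. RNA quality or labelling from the 3′ end stays open. The rule set beforehand took a median log2 difference at least 0.1 above that of the other tested probes as a sign of it. The 10161 tested probes with AATAAA lay 0.0332 above the others, under that margin, which argues against a shift of the class as a whole. The middle 50% of them ran from −0.11 to 0.16, a spread the rule left out. An effect of RNA quality or labelling need not shift every probe alike. A hypothesis also left open is that changed probes, and the strongly raised ones most, lie more often at the ends of polyadenylated transcripts, which may reflect stroke or the slide and was not tested against a genome.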
